A study of Mus musculus with 9 samples.

How the data were processed

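RNA sequencing was made from spleen cells of 16-week-old mice in 3 groups of 3 animals: females of the NZB x NZW F1 cross (BWF1), which the series title names as prone to lupus, BWF1 males and BALB/c females, which it names as not prone. The labels disagree on what was sequenced. The title and the design text speak of splenocytes, whereas the sample labels name macrophages sorted for CD11b and F4/80 after collagenase digestion, so the levels of cell type markers are given as values. The library kits depleted ribosomal RNA and were not described as marking the strand, per the labels' protocols.

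The deposited values were raw read counts per gene, 1 file per library, with the 5 summary lines that HTSeq writes at the end of each. STAR 2.6, FastQC 0.10.1 and the genome build mm10 are named in the submitters' processing notes, without roles or order. The annotation release, the strand setting and the feature type of the counting are not given, so reads of overlapping and antisense genes cannot be told apart. The files held 21965 Ensembl gene identifiers, of which 21882 were protein-coding in GENCODE M21, 21939 matched that annotation and 26 did not. Names and coordinates were taken from GENCODE M21 on mm10. The series table and the files of the single libraries differed in 0 values. Many immunoglobulin and T cell receptor genes, and Xist, were not among the identifiers counted. File names carried the tag ORIG in 5 libraries (BWF1 male 2, BWF1 female 2 and all BALB/c) and RL in 4 (BWF1 males 1 and 3, BWF1 females 1 and 3). The labels do not say what the tag means.

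The depth was low. Gene counts ranged from 458608 in BWF1 female 1 to 4305003 in BWF1 male 3, and the counts left after removing Lars2 from 188382 to 2050636. A gene with 3 counts in a single library stood at between 0.697 and 6.54 CPM (counts scaled to a fixed library total). These floors use raw library totals, whereas the levels given below are TMM-scaled. In BWF1 male 1, with the lowest TMM factor (0.530), the floor on that scale lies above the 3.09 CPM of its raw total. For genes with 0 counts in a group, fold changes were bounded with 3 counts over the TMM-scaled sizes of its libraries together, a floor of 1.92 CPM in BWF1 females, 0.477 CPM in BWF1 males and 0.765 CPM in BALB/c females. Reads carried no molecular identifiers, so floors and intervals cover counting error only. Between replicates of a group, the chi-square per degree of freedom over genes ran from 1.27 to 3.13, where counting error alone gives about 1.

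Differences were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 7719 genes and set aside 14246, of which 6689 had a count of 0 in all 9 libraries. Libraries were scaled with TMM factors, which ran from 0.530 in BWF1 male 1 to 1.40 in BALB/c female 2. A quasi-likelihood negative binomial model was fitted to all 9 libraries (prior degrees of freedom 19.4), and each of 3 comparisons was tested with the quasi-likelihood F test. P-values were adjusted over all tested genes by Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. Values per group are TMM-scaled CPM as mean ± SD with n = 3. Single measures per library were compared with exact permutation tests, two-sided, for which 3 against 3 allows no p under 0.1.

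Gene lists for cell types, macrophage functions, interferon responses, X-linked genes, cell division and dissociation stress were fixed before the data were examined, as were the tests, the rule for named genes and all alternatives not marked as added. Of them, 28 had at least 3 tested members. The lists for sex label checks, marginal zone and tingible body macrophages, eosinophils, megakaryocytes and platelets, and mast cells and basophils had too few tested members for a test. Each list was tested with camera (limma 3.58.1, preset correlation 0.01) on log2 CPM with a prior count of 2, adjusted over 84 tests (28 lists, 3 comparisons), and again with an estimated correlation and with fry. Of the 84 tests, 41 passed with the preset correlation and 0 with an estimated one, where 20 had an unadjusted p under 0.05. By fry, 39 moved on balance in one direction and 66 in either. The T cell, natural killer cell, erythroid, plasma cell, neutrophil and proliferation lists share 0 members with other lists. In other lists up to 8 members also stand in another list. All list calls below are therefore given with both p-values.

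The genes named are, for each comparison, called genes whose groups do not overlap and whose mean is at least 5 CPM in the higher group: the 10 largest changes and the 5 lowest p-values in each direction, without predicted genes and receptor segments. They also include the 2 members of each list with the lowest p in each direction among called members, or the member with the lowest p where the list has no called member, and the sex label genes, Adgre1, Itgam, Tlr7, Tnfsf13b, Ifi202b and Fcgr2b. For calls shared by both comparisons of BWF1 females, they are the 10 in each direction with the largest smaller fold change. A gene was left unnamed where a paragraph would only repeat statistics. Lars2, Gm26992, Ccnb1ip1, Ccdc107, Hba-a1 and any member of a list or family outside this rule were chosen after their values were seen. Itgam, Tnfsf13b and Ifi202b lay below the count filter.

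The test was checked on simulated counts drawn from the means and library sizes of these libraries, with 200 changed genes in each of 5 simulations. At a fold change of 4 it recovered 85.2% of changed genes for BWF1 females against BWF1 males (7028 genes in the step), 87.6% for BWF1 females against BALB/c females (7343 genes) and 92.7% for BWF1 males against BALB/c females (7344 genes). At a fold change of 2 the shares were 44.5%, 47.8% and 56.1%, and at 1.5 they were 9.85%, 11.9% and 15.5%. False calls made up 3.54%, 6.50% and 3.36% of all calls.

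The alternatives tried were DESeq2 1.42.0, limma-voom, other scalings (RLE, upper quartile, library size only), no count filter and a stricter one of 5 CPM, only the 2 groups compared, robust dispersion, a test against a fold of 1.5, a replicate block, the file-name tag as a covariate, RL libraries only, removal of 13 immunoglobulin, haemoglobin, T cell receptor and mitochondrial genes, and leaving out each library in turn. Added after the data were seen were removal of Lars2, Ccnb1ip1 and Ccdc107, thinning of every library to 188382 counts outside Lars2, and ORIG libraries only. Lars2 transcripts were compared with all annotated transcripts with blastn 2.17.0. Random steps used seed 11.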

Results

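Gene counts were obtained from 9 spleen libraries of 16-week-old mice, 3 each from BWF1 females, BWF1 males and BALB/c females. The totals over genes were 458608, 673160 and 469329 in BWF1 females 1 to 3, 970263, 1047510 and 4305003 in BWF1 males 1 to 3, and 1310639, 1112803 and 879890 in BALB/c females 1 to 3. Between 11095 and 13744 genes had at least 1 count. Few alignments fell in the counted genes, 1.29% to 2.82% per library. Another 37.2% to 42.1% overlapped no counted feature, and 55.9% to 61.5% were not unique. The former can include reads in genes that were not counted. Lars2, the mitochondrial leucyl-tRNA synthetase (ENSMUSG00000035202, mm10 chromosome 9, 123366927 to 123462666), held 42.3% to 76.6% of the gene counts. Its share was 59.3% ± 2.70 (SD, n = 3) in BWF1 females, 63.2% ± 12.3 in BWF1 males and 49.8% ± 6.96 in BALB/c females. By exact two-sided permutation tests of this share, p = 0.8 for BWF1 females against BWF1 males, 0.1 for BWF1 females against BALB/c females and 0.2 for BWF1 males against BALB/c females, where 0.1 is the smallest p that 3 against 3 allows. The total gene counts of BWF1 females were lower than those of both other groups (exact p = 0.1 in each comparison).

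**Figure D1:**
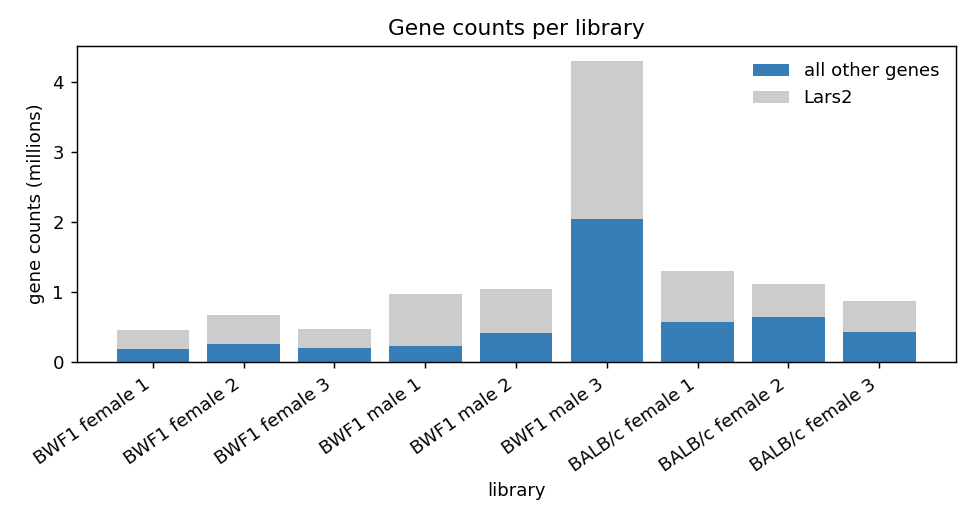
Gene counts of each library, as bars stacked from Lars2 (grey) and all other genes (blue). BWF1 male 3 had 4305003 counts, while the 3 BWF1 female libraries had 458608 to 673160.

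The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y matched the sex labels. Each had 0 counts in all 6 female libraries and 126, 152, 116 and 126 counts over the 3 male libraries. Gm26992, which overlaps Xist on the X chromosome, had 12 to 42 counts in each female library and 0 in the male ones.

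Markers of several cell types were present in every group. The markers of the sorting gate and of macrophages summed to 898 ± 63.3 CPM in BWF1 females, 1232 ± 147 in BWF1 males and 1198 ± 118 in BALB/c females (n = 3). That list includes Ptprc, the general leukocyte gene CD45, so its sum is not of macrophages alone. B cell markers summed to 3065 ± 136, 3292 ± 400 and 4057 ± 31.1 CPM in the same order, and T cell markers to 571 ± 51.6, 985 ± 111 and 742 ± 104 CPM. Erythroid markers varied between libraries of a group, at 1562 ± 1013, 611 ± 709 and 2624 ± 1651 CPM. Adgre1, which encodes F4/80, stood at 14.8 ± 2.7, 15.3 ± 5.0 and 7.27 ± 1.8 CPM and was not called in any comparison. Itgam, which encodes CD11b, lay below the count filter. As the mean log2(CPM + 1) over detected members, B cell markers ran from 7.59 to 8.17 across libraries and the gate list from 3.83 to 5.01. These levels argue against libraries made up mostly of sorted macrophages. Changes in macrophage genes therefore cannot be placed in such sorted cells. Immunoglobulin and T cell receptor constant genes were not analysed here.

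BWF1 females, the lupus-prone group, were first compared with BWF1 males, which share their strain and age. Genes of cytotoxic lymphocytes were lower in the females. Perforin (Prf1, ENSMUSG00000037202, mm10 chromosome 10, 61297833 to 61304680) fell from 60.0 ± 8.3 CPM in males to 10.6 ± 5.2 in females, a log2 fold change of −2.53 (SE 0.29; edgeR adjusted p = 9.04e-06). Granzyme A (Gzma) fell from 93.0 ± 13 to 22.5 ± 1.9 CPM (−2.04, SE 0.24; adjusted p = 1.02e-05). Cd8a, a chain of the CD8 coreceptor, fell by 1.75, the chemokine Ccl5 by 1.94 and the interleukin-2 receptor chain Il2rb by 1.37 on the log2 scale. The macrophage genes Csf1r (the receptor for colony stimulating factor 1), Vcam1, Mrc1, Lyz2 and the complement component gene C1qa also fell, by 1.62, 1.63, 1.84, 1.40 and 2.09. Of these genes, Prf1, Cd8a, Ccl5 and Lyz2 were also called lower in BWF1 females than in BALB/c females. Gzma, Il2rb, Csf1r, Vcam1, Mrc1 and C1qa were not. Csf1r stood at 30.9 to 48.4 CPM in BWF1 females, 40.6 to 52.6 in BALB/c females and 84.1 to 149 in BWF1 males.

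Jchain, which joins the subunits of secreted IgM and IgA in plasma cells, fell from 1239 ± 342 to 392 ± 82 CPM (log2 fold change −1.66, SE 0.19; edgeR adjusted p = 9.04e-06). In BALB/c females it stood at 405 to 572 CPM, and it was not called lower in BWF1 females than there. Higher in BWF1 females than in BWF1 males were the histone demethylase gene Kdm6a, the complement gene C4b, the collagen gene Col1a2 and the cell division gene Mki67. Kdm6a (ENSMUSG00000037369, mm10 chromosome X, 18162575 to 18279936) is described as escaping X inactivation and rose from 35.5 ± 0.81 CPM to 121 ± 9.1 (log2 fold change 1.77, SE 0.18; edgeR adjusted p = 1.71e-06). It was also higher in BWF1 females than in BALB/c females, which share their sex (log2 fold change 0.79, edgeR adjusted p = 0.00738). C4b (ENSMUSG00000073418, chromosome 17, 34728380 to 34743882) rose from 2.27 ± 1.5 to 16.6 ± 5.8 CPM (3.03, SE 0.53; adjusted p = 0.00158), a gene with a close copy, so its counts are uncertain. Col1a2 (ENSMUSG00000029661, chromosome 6, 4504814 to 4541544) rose from 1.21 ± 1.1 to 17.1 ± 9.4 CPM (3.52, SE 0.59; adjusted p = 0.00111). Of the 221 X-linked genes tested, 4 were higher and 2 lower. For every gene named here with a fold change, the 3 female libraries lay on one side of the 3 male libraries.

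By list, the T cell markers moved together. Of 15 tested members, 8 fell and 7 did not pass, while all 15 had a negative fold change. The count was 11 adjusted over the list alone (median log2 fold change −0.84; camera adjusted p = 4.35e-09, and adjusted p = 0.142 with an estimated correlation). The count of 8 was 4 without BWF1 male 2, 2 without BWF1 male 3, 5 without BWF1 female 2, 4 without BWF1 female 3 and 5 without BALB/c female 3. Of 8 natural killer cell markers, 4 fell (Prf1, Gzma, Klrb1c and Nkg7), or 6 adjusted over the list alone (median −1.34; camera adjusted p = 4.96e-08, and adjusted p = 0.0926 with an estimated correlation). Of 26 proliferation genes, 3 rose (Mki67, Top2a and Rrm2), or 12 adjusted over the list alone, with a median of 0.76 (camera adjusted p = 4.96e-08, and adjusted p = 0.233 with an estimated correlation). Mki67 was highest in BWF1 female 3 (312 CPM) and BALB/c female 2 (307 CPM), the libraries with the highest summed erythroid markers (2725 and 4522 CPM), and its call ended with DESeq2 and with robust dispersion. Rrm2, at 82.1 CPM in BWF1 female 3, was no longer called without that library (edgeR adjusted p = 0.079).

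Lists of myeloid cells were lower in females as well. Of 9 members of the macrophage gate list, Csf1r and Lyz2 fell, or 4 adjusted over the list alone (median −0.58; camera adjusted p = 0.0111, and adjusted p = 0.254 with an estimated correlation). Of 9 complement genes, C4b rose while C1qa and C1qc fell, with 1 up and 5 down adjusted over the list alone (median −0.61; camera adjusted p = 0.00862, and adjusted p = 0.289 with an estimated correlation). The complement count of 3 became 5 without BWF1 female 1. The red pulp macrophage and iron list (median −0.41; camera adjusted p = 0.00717, and adjusted p = 0.254 with an estimated correlation) had 1 up and 7 down of 19 adjusted over the list alone, and Vcam1 and Lrp1 lower over all genes. That count was 1 without BWF1 male 3, BWF1 female 2 or any single BALB/c library. Monocyte markers had a median of −0.68 (camera adjusted p = 0.00445, and adjusted p = 0.208 with an estimated correlation) and 2 lower over all genes, or 1 up and 5 down of 12 adjusted over the list alone. That count was 0 without BWF1 male 2 and 1 without BWF1 female 1, 2 or 3. Neutrophil markers had a median of −0.88 (camera adjusted p = 0.0111, and adjusted p = 0.436 with an estimated correlation) and 5 of 9 lower adjusted over the list alone. Over all genes, 0 of the 9 were called by edgeR, DESeq2 or limma-voom, and 5 had an unadjusted edgeR p under 0.05. By edgeR, 5 were called without BWF1 female 3 and 1 without BWF1 male 2.

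Alternative activation had Mrc1 lower, or 1 of 5 adjusted over the list alone (median −0.48; camera adjusted p = 0.0201, and adjusted p = 0.208 with an estimated correlation). Inflammatory cytokines had Il1b and Ccl5 lower over all genes and 4 of 10 lower adjusted over the list alone (median −0.48; camera adjusted p = 0.00717, and adjusted p = 0.208 with an estimated correlation). Only 1 was called without BWF1 male 1, BWF1 female 1 or BWF1 female 3. Antigen presentation had Cd74 and B2m lower over all genes and 1 up and 5 down of 23 adjusted over the list alone (median −0.22; camera adjusted p = 0.0125, and adjusted p = 0.295 with an estimated correlation). Its count was 1 without BWF1 male 1, BWF1 female 2 or BALB/c female 2 and 0 without BWF1 males 2 or 3 or BWF1 females 1 or 3. Lipid handling passed with a median of −0.18 (camera adjusted p = 0.0258, and adjusted p = 0.208 with an estimated correlation). Of its 19 members, 0 were called by edgeR over all genes or adjusted over the list alone, and 0 by DESeq2 or limma-voom, while 3 had an unadjusted edgeR p under 0.05. The immediate early and heat shock list had Hspa1b higher and Fos, Hspa8 and Hsph1 lower (median −0.39; camera adjusted p = 0.00896, and adjusted p = 0.486 with an estimated correlation), or 2 up and 6 down of 25 adjusted over the list alone. Its 4 calls became 1 without BWF1 male 3 and 2 without BWF1 female 1 or 2. Erythroid markers had a median of 1.87 (camera adjusted p = 0.00138, and adjusted p = 0.429 with an estimated correlation) and 8 of 11 higher adjusted over the list alone. Over all genes 1 was called, Epb42, against 8 without BWF1 male 1, 0 without BWF1 male 2, BWF1 male 3 or BWF1 female 3, 2 without BWF1 female 1, and 3 without BWF1 female 2 or BALB/c female 2.

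The interferon-stimulated genes, often raised in lupus, did not pass camera between BWF1 females and males (adjusted p = 0.952), with 19 of 41 members tested. Ifit1, Ifit3, Isg15, Mx1, Oas1a and Usp18 were among the members below the count filter, and Mx2 was not among the identifiers counted. Most of the list was therefore not tested. Rsad2, an antiviral gene of that list, stood at 41.2 ± 8.8 CPM in females and 13.9 ± 17 in males (log2 fold change 1.97, SE 0.54; edgeR adjusted p = 0.0511). Tlr7, the X-linked receptor for single-stranded RNA, stood at 13.8 ± 4.3 and 21.6 ± 11 CPM (−0.69, SE 0.38; adjusted p = 0.374), and Fcgr2b, the inhibitory Fc receptor, at 29.9 ± 7.7 and 37.9 ± 1.4 CPM (−0.32; adjusted p = 0.558). By camera, adjusted p was 0.929 for X-linked immune and escape genes, 0.945 for the p200 family, 0.316 for interferon-gamma-inducible genes, 0.158 for Fc receptors, 0.176 for clearance of apoptotic cells, 0.733 for Toll-like receptors and inflammasomes, 0.416 for glycolysis and 0.248 for steroid signalling. It was 0.755 for conventional and 0.152 for plasmacytoid dendritic cells, 0.721 for B cells, 0.0505 for plasma cells and 0.628 for stromal and endothelial cells. The median, the mean and the test differed in sign for the X-linked, interferon-stimulated and stromal lists.

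In all, edgeR called 169 of 7719 genes between BWF1 females and males, 74 higher and 95 lower in females, and 1266 had an unadjusted p under 0.05. The groups did not overlap for 163 of the called genes and for 18.7% of all tested genes, where chance gives 10%. The count was 58 without BWF1 male 3, 101 without BWF1 male 2 and 108 without BWF1 female 3, and it was 59 (45 higher, 14 lower) with library size only as the scaling, which shifted the median gene by 0.16 and ended the calls of 26 of the 61 named genes called, among them Il2rb, Lyz2, C1qc, Il1b, B2m, Cd74, Lrp1, Fos, Hspa8 and Trib1. DESeq2 called 108 genes and ended the calls of 35 of the 61, of which 30, among them C4b, Col1a2, C1qa, C1qc, Mrc1, Rrm2, Pclaf, Tgfbi, Trib1 and the Y-linked genes, got no adjusted p through its filter on mean counts.

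**Figure D2:**
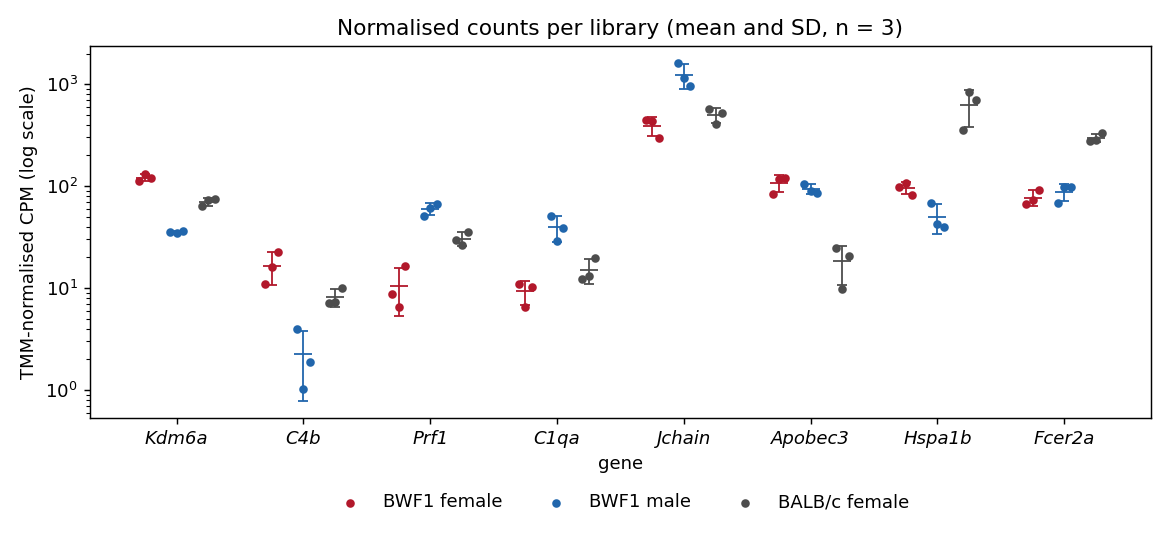
TMM-scaled CPM on a log axis for Kdm6a, C4b, Prf1, C1qa, Jchain, Apobec3, Hspa1b and Fcer2a, with 1 point per library and the mean and SD of each group (n = 3). Prf1 was lowest in BWF1 females at 10.6 ± 5.2 CPM, Apobec3 was lowest in BALB/c females at 18.4 ± 7.6 CPM, and Hspa1b was highest in BALB/c females at 629 ± 251 CPM.

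BWF1 females were next compared with BALB/c females, which share their sex and age but not their strain. Genes of the stress response and of early activation were lower in BWF1 females. The inducible heat shock gene Hspa1b (ENSMUSG00000090877, mm10 chromosome 17, 34956436 to 34959238) stood at 95.8 ± 13 CPM in BWF1 females and 629 ± 251 in BALB/c females (log2 fold change −2.71, SE 0.24; edgeR adjusted p = 9.81e-08). Its near-identical neighbour Hspa1a moved with it (−2.37), so that reads cannot be assigned to one of the pair with certainty. Fcer2a (CD23, ENSMUSG00000005540, chromosome 8, 3681737 to 3694175), a low-affinity IgE receptor of mature B cells, fell from 298 ± 29 to 77.1 ± 14 CPM (−1.95, SE 0.18; adjusted p = 1.1e-07). The inflammatory cytokine Il1b fell from 89.2 ± 6.6 to 17.0 ± 9.2 CPM (−2.35, SE 0.34; adjusted p = 9.38e-05). Higher in BWF1 females were the restriction factor Apobec3 (ENSMUSG00000009585, chromosome 15, 79891659 to 79915906), at 108 ± 21 against 18.4 ± 7.6 CPM (2.56, SE 0.25; adjusted p = 3.52e-07), and Ly6a (Sca-1, ENSMUSG00000075602, chromosome 15, 74994877 to 74998031), at 53.7 ± 24 against 7.16 ± 1.4 CPM (2.90, SE 0.30; adjusted p = 7.91e-07).

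Further genes rose in BWF1 females. The interferon-induced membrane protein gene Ifitm2 had a log2 fold change of 2.24, Coro2a 2.95, Padi2, which converts arginine to citrulline, 2.55, the chaperone Pdia4 1.11 and the replication helicase subunit Mcm6 1.28. Pld5 had 0 counts in BALB/c females and was at least 18.4-fold higher, against 3 counts over the group (11.3-fold without BALB/c female 2). Lower were Ccl5 (−1.93), the ICOS ligand Icosl (−1.16), the MHC class II gene H2-Aa (−0.84), Apoe (−1.01), Lyz2 (−1.09) and Tgfbi (−1.89). Ly6c1, which has close relatives in its gene cluster, had 0 counts in BWF1 females and was at least 8.35-fold lower (5.04-fold without BWF1 female 2). Haemoglobin alpha Hba-a2 (ENSMUSG00000069917, chromosome 11, 32296489 to 32297298) had 0 counts in all 6 BWF1 libraries and 1082 over the BALB/c libraries, at least 143-fold lower in BWF1 females (a call that ended with robust dispersion). BALB/c female 2 held 720 of the 1082 counts, and without it the bound was 78.4-fold. The near-identical copy Hba-a1 had raw totals of 622 counts in BWF1 females, 573 in BWF1 males and 1627 in BALB/c females. These totals are not scaled for depth, which was lowest in BWF1 females, so they do not compare levels between the groups. For each gene of these paragraphs with a fold change, the 3 libraries of one group lay on one side of those of the other.

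By list, the immediate early and heat shock genes fell. Of 25 tested members, 15 fell, among them Hspa1b, Hspa1a, Klf6, Nr4a1, Fos and Jun, and 10 did not pass. The count adjusted over the list alone was 18 (median −0.86; camera adjusted p = 7.39e-13, and adjusted p = 0.208 with an estimated correlation). Of 10 inflammatory cytokines, 6 fell (Il1b, Ccl5, Tnf, Ccl3, Cxcl13 and Ptgs2), or 8 adjusted over the list alone (median −1.80; camera adjusted p = 4.96e-08, and adjusted p = 0.0926 with an estimated correlation). That count was 3 without BWF1 female 2 or BALB/c female 3. Of 23 antigen presentation genes, 4 fell (H2-Aa, H2-Oa, Cd40 and Icosl), or 6 adjusted over the list alone (median −0.29; camera adjusted p = 0.00499, and adjusted p = 0.257 with an estimated correlation). Of 17 genes for the clearance of apoptotic cells, 4 fell (Mfge8, a bridge between dying cells and phagocytes, Dnase1l3, an extracellular DNase, Stab2 and Cd93), or 5 adjusted over the list alone (median −0.26; camera adjusted p = 0.0201, and adjusted p = 0.293 with an estimated correlation).

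Marker lists of B, T and stromal cells were lower in BWF1 females. Of 13 B cell markers, 4 fell (Fcer2a, Cr2, Cd22 and Cd79a), and 4 adjusted over the list alone (median −0.22; camera adjusted p = 0.00397, and adjusted p = 0.233 with an estimated correlation). The count was 1 without BWF1 female 1 and 2 without any single BALB/c library. Of 15 T cell markers, Cd3g and Cd8a fell, and 2 adjusted over the list alone (median −0.44; camera adjusted p = 0.00445, and adjusted p = 0.254 with an estimated correlation). Of these, 1 was called without BWF1 female 2 or BALB/c female 3. Of 6 stromal and endothelial markers, Kdr and Stab2 fell, or 3 adjusted over the list alone (median −1.03; camera adjusted p = 0.00445, and adjusted p = 0.208 with an estimated correlation). Their count was 1 without BWF1 female 1, BALB/c female 1 or BALB/c female 2. Of 7 conventional dendritic cell markers, Ccr7 and Naaa fell, or 3 adjusted over the list alone (median −0.32; camera adjusted p = 0.0328, and adjusted p = 0.208 with an estimated correlation). Erythroid markers had Hba-a2 lower of 11, and 1 adjusted over the list alone (median −0.44, the same with Hba-a2 at its bound; camera adjusted p = 0.0127, and adjusted p = 0.522 with an estimated correlation). The count was 6 without BWF1 female 3 and 2 without BWF1 male 1.

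Of the other lists that passed, Toll-like receptors and inflammasomes had 4 of 28 lower (Tlr11, Nfkbia, Tnfaip3 and Nlrc4), and 4 adjusted over the list alone (median −0.19; camera adjusted p = 0.0137, and adjusted p = 0.208 with an estimated correlation). The count was 1 without BWF1 female 2 or BALB/c female 3 and 2 without BWF1 female 3, BALB/c female 1 or BALB/c female 2. Red pulp macrophage and iron genes had Hmox1 and Ftl1 lower, or 2 up and 6 down of 19 adjusted over the list alone (median −0.46; camera adjusted p = 0.0181, and adjusted p = 0.293 with an estimated correlation). Their count was 0 without BALB/c female 2 or 3 and 1 without BWF1 male 3. Fc receptors had Fcer2a lower of 7, or 2 adjusted over the list alone (median −0.06; camera adjusted p = 0.0353, and adjusted p = 0.208 with an estimated correlation). Proliferation genes had Mcm6 higher of 26, and 1 adjusted over the list alone, with a median of 0.21 that became −0.08 with library size only, by the shift of −0.29 that this scaling gives the median gene (camera adjusted p = 0.0181, and adjusted p = 0.522 with an estimated correlation). Their count was 2 without BWF1 female 1.

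The interferon-stimulated genes did not pass camera here either (adjusted p = 0.616, on the same 19 members). Adjusted p was 0.479 for X-linked genes, 0.945 for the p200 family, 0.151 for interferon-gamma-inducible genes, 0.616 for complement, 0.832 for alternative activation, 0.516 for glycolysis, 0.0837 for lipid handling and 0.317 for steroid signalling. For cell types it was 0.530 for the macrophage gate, 0.276 for monocytes, 0.331 for neutrophils, 0.625 for plasmacytoid dendritic cells, 0.242 for plasma cells and 0.242 for natural killer cells. The median, the mean and the test differed in sign for alternative activation and monocytes. Some lists that did not pass still held called members. Among them, 1 interferon-stimulated gene was lower, 1 interferon-gamma-inducible gene higher, and of the neutrophil markers 1 was higher and 2 lower. Without single libraries these counts ran from 0 to 2, 0 to 2 and 1 to 3.

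Between BWF1 and BALB/c females, edgeR called 295 of 7719 genes, 138 higher and 157 lower in BWF1 females, and 1308 had an unadjusted p under 0.05. The groups did not overlap for 289 of the called genes and for 21.2% of all tested genes, where chance gives 10%. The count was 184, 189 and 194 without BALB/c female 1, 2 and 3, and 130 (23 higher, 107 lower) with library size only, which shifted the median gene by −0.29 and ended the calls of 24 of the 71 named genes called, among them Pdia4, Mcm6, Nr4a1, Ftl1, Hmox1, Cr2, Pclaf, Crebzf, Safb2 and Luc7l3. With the file-name tag as a covariate 160 genes were called, and no BALB/c library carries the tag RL, so tag and strain overlap in this comparison.

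**Figure D3:**
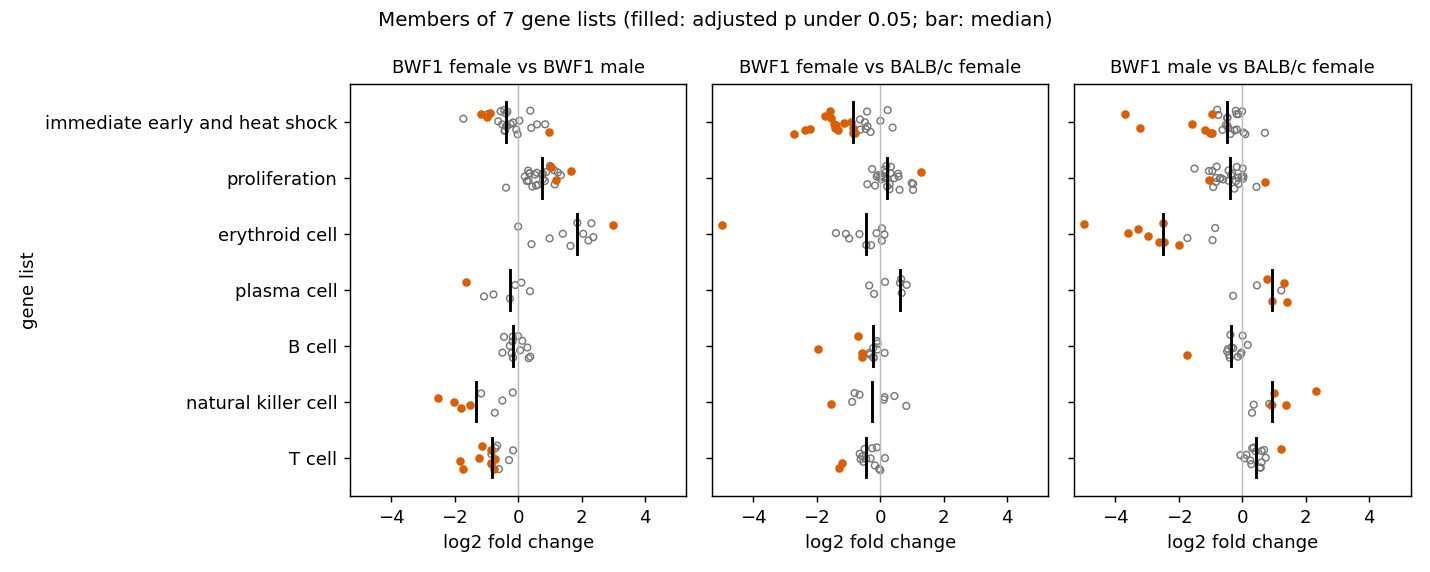
Log2 fold changes of the tested members of gene lists in the 3 comparisons, 1 point per gene, filled where the edgeR adjusted p is under 0.05, with a bar at the median; Hba-a2 lies beyond the axis and is drawn at its limit of 5. T cell markers had a median of −0.84 and natural killer cell markers of −1.34 in BWF1 females against BWF1 males, and immediate early and heat shock genes of −0.86 in BWF1 females against BALB/c females.

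BWF1 males and BALB/c females, both named as not lupus-prone, differ in strain and in sex, and neither can be separated from the other in their comparison. Ly6a was higher in BWF1 males at 84.8 ± 14 against 7.16 ± 1.4 CPM (log2 fold change 3.54, SE 0.29; edgeR adjusted p = 9.38e-09). Also higher were Ifitm2 (3.48, SE 0.30; adjusted p = 1.86e-08), Coro2a (3.41), Padi2 (3.13), Apobec3 (2.35), Ly6d (2.09) and Pdia4 (1.42). Klrb1c, the natural killer cell receptor NK1.1, rose from 4.33 ± 1.3 to 22.2 ± 0.55 CPM (2.34, SE 0.36; edgeR adjusted p = 0.000152). Gzma rose by 1.38 on the log2 scale, Jchain by 1.31 and Csf1r by 1.39. Hspa1b fell from 629 ± 251 to 50.1 ± 16 CPM (−3.69, SE 0.25; edgeR adjusted p = 2.75e-10). Fcer2a fell from 298 ± 29 to 88.1 ± 17 CPM (−1.74, SE 0.17; adjusted p = 1.98e-07) and Col1a2 from 13 ± 2.2 to 1.21 ± 1.1 CPM (−3.17, SE 0.56; adjusted p = 0.00061). Ddx3y and Eif2s3y were at least 26.2-fold higher and Pld5 at least 21.4-fold, while Hba-a2 was at least 578-fold lower and Gm26992 at least 55.6-fold lower in the males. Without BWF1 male 3 the bound of Hba-a2 was 137-fold and that of Gm26992 13.1-fold. Without BALB/c female 2 it was 16.0-fold for Ddx3y and Eif2s3y, 13.1-fold for Pld5 and 316-fold for Hba-a2. Kdm6a fell by 0.98 (edgeR adjusted p = 0.00101).

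By list, erythroid markers fell in BWF1 males: 8 of 11 over all genes and 9 adjusted over the list alone (median −2.49, the same with Hba-a2 at its bound; camera adjusted p = 3.63e-09, and adjusted p = 0.225 with an estimated correlation). The count of 8 was 5 without BWF1 male 2, 4 without BWF1 male 3 and 3 without BALB/c female 2. The summed level of erythroid markers ran from 199.7 CPM in BWF1 male 3 to 1429.8 CPM in BWF1 male 1. Natural killer cell markers rose: 4 of 8 (Klrb1c, Gzma, Prf1 and Nkg7), or 6 adjusted over the list alone (median 0.93; camera adjusted p = 9.37e-07, and adjusted p = 0.101 with an estimated correlation). Their count was 2 without BWF1 male 2, BWF1 male 3, BALB/c female 1 or BALB/c female 2. Of 7 plasma cell markers, 4 rose (Jchain, Xbp1, the transcription factor of the secretory programme, Sdc1 and Mzb1), or 5 adjusted over the list alone (median 0.92; camera adjusted p = 0.000889, and adjusted p = 0.208 with an estimated correlation). Their count was 2 without BWF1 male 1, BWF1 male 2 or BALB/c female 2.

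The immediate early and heat shock genes were lower in BWF1 males as they were in BWF1 females: 7 of 25 fell, among them Hspa1b, Hspa1a and Jun, with 1 up and 10 down adjusted over the list alone (median −0.47; camera adjusted p = 2.15e-07, and adjusted p = 0.254 with an estimated correlation). Of 10 inflammatory cytokines, 3 fell (Tnf, Cxcl13 and Ptgs2), or 4 adjusted over the list alone (median −0.90; camera adjusted p = 0.00189, and adjusted p = 0.208 with an estimated correlation). That count was 5 without BWF1 male 1 and 1 without BALB/c female 1 or 2. Of 9 complement genes, C1qa, C1qb, C1qc and Itgb2 rose and C4b fell, and 4 up and 1 down adjusted over the list alone, with a median of 0.45 that became −0.02 with library size only, by the shift of −0.44 that this scaling gives the median gene (camera adjusted p = 0.0289, and adjusted p = 0.381 with an estimated correlation). The complement count of 5 was 3 without BWF1 male 2, BWF1 male 3 or BALB/c female 1 and 2 without BALB/c female 2.

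Further lists passed on few called members. T cell markers had a median of 0.42 (camera adjusted p = 0.000889, and adjusted p = 0.208 with an estimated correlation) and 3 of 15 higher adjusted over the list alone, with Cd8b1 called over all genes. Its call ended without BWF1 male 2 (edgeR adjusted p = 0.075), BWF1 male 3 (0.17), BALB/c female 1 (0.13) and BALB/c female 2 (0.15), and 2 members were called without BWF1 male 1. Alternative activation had a median of 0.63 (camera adjusted p = 0.0189, and adjusted p = 0.208 with an estimated correlation) with Mrc1 and Cd163 higher, and 2 of 5 adjusted over the list alone. That count was 1 without BWF1 male 2 or BALB/c female 2 and 0 without BWF1 male 3. The macrophage gate list had a median of 0.37 (camera adjusted p = 0.0314, and adjusted p = 0.308 with an estimated correlation), with Csf1r higher of 9, or 2 adjusted over the list alone, and 2 called without BWF1 male 1. B cell markers had a median of −0.34 (camera adjusted p = 0.00445, and adjusted p = 0.246 with an estimated correlation), with Fcer2a lower of 13, or 4 adjusted over the list alone, and 2 called without BWF1 male 1 or BWF1 female 3. Stromal and endothelial markers had a median of −0.67 (camera adjusted p = 0.00403, and adjusted p = 0.208 with an estimated correlation), with Col1a2 lower of 6, or 3 adjusted over the list alone. Their count was 3 without BWF1 male 1, BWF1 female 1 or BWF1 female 3 and 2 without BWF1 males 2 or 3, BWF1 female 2 or BALB/c females 1 or 3.

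Conventional dendritic cell markers had a median of −0.55 (camera adjusted p = 0.0266, and adjusted p = 0.208 with an estimated correlation), with Naaa lower of 7, or 4 adjusted over the list alone. Their count was 0 without BWF1 males 2 or 3 or BALB/c females 1 or 2, 2 without BWF1 male 1, BWF1 female 1 or BALB/c female 3, and 4 without BWF1 female 3. Toll-like receptors and inflammasomes had Tlr11 and Tnfaip3 lower of 28, or 5 adjusted over the list alone (median −0.30; camera adjusted p = 0.0236, and adjusted p = 0.208 with an estimated correlation). Proliferation genes had Mki67 lower and Mcm6 higher of 26, and 1 up and 2 down adjusted over the list alone (median −0.39; camera adjusted p = 0.0044, and adjusted p = 0.436 with an estimated correlation). Their count was 0 without BALB/c female 2 and 1 without BWF1 male 3, BALB/c female 1 or BALB/c female 3. Camera's adjusted p was 0.264 for X-linked genes, 0.616 for interferon-stimulated genes, 0.929 for the p200 family, 0.705 for interferon-gamma-inducible genes, 0.616 for antigen presentation, 0.445 for Fc receptors, 0.248 for clearance of apoptotic cells and 0.755 for red pulp macrophages and iron. It was 0.855 for glycolysis, 0.721 for lipid handling, 0.984 for steroid signalling, 0.165 for monocytes, 0.179 for neutrophils and 0.12 for plasmacytoid dendritic cells. The median, the mean and the test differed in sign for the p200 family, red pulp macrophages and iron, and steroid signalling. Lists that did not pass could hold calls in both directions. Clearance of apoptotic cells had 6 called, 3 higher and 3 lower, and red pulp macrophages and iron had 5, 3 higher and 2 lower. Without single libraries these counts ran from 2 to 6 and from 1 to 6.

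Between BWF1 males and BALB/c females, edgeR called 272 of 7719 genes, 129 higher and 143 lower in the males, and 1260 had an unadjusted p under 0.05. The groups did not overlap for 266 of the called genes and for 23.5% of all tested genes, where chance gives 10%. The count was 150 without BWF1 male 3 and 119 without BALB/c female 2, and with library size only it was 274 (26 higher, 248 lower), a scaling that shifted the median gene by −0.44 and ended the calls of 16 of the 66 named genes called, among them Gzma, Jchain, Csf1r, C1qa, C1qc, Xbp1, Pdia4, Mrc1, Mcm6 and Cd8b1. The call of Hba-a2 ended with robust dispersion, and 153 genes were called with the file-name tag as a covariate.

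Genes that set BWF1 females apart from both groups were taken from the 2 comparisons that share the BWF1 female libraries. In the same direction in both, 43 genes were called, 21 higher and 22 lower. Higher was Pclaf, a partner of the replication clamp PCNA, at 29.3 ± 2.5 CPM against 7.86 ± 2.7 in BWF1 males and 8.79 ± 1.0 in BALB/c females (log2 fold changes 1.79 and 1.74). The RNA-binding protein genes Safb2 (1.14 and 1.00) and Luc7l3 (1.11 and 0.97), and Crebzf (1.42 and 1.17) were also higher. Lower were Ccl5 (−1.94 and −1.93), Prf1 (−2.53 and −1.54), Lyz2 (−1.40 and −1.09) and Trib1, a pseudokinase (−1.71 and −1.90). Tgfbi (−1.87 and −1.89) was no longer called against BWF1 males without BWF1 male 3 (edgeR adjusted p = 0.057).

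Independent lists of these sizes would share 1.32 higher and 1.93 lower genes, and 50 simulations without any effect, in which the comparisons share the same libraries, gave 0.1 shared genes on average and 2 at most. Opposite directions were called for 3 genes. Over all tested genes the correlation of the fold changes was 0.48, against 0.68 in the simulations, and their covariance was 0.135 against 0.0710. BWF1 female and male libraries shared 43 higher and 65 lower genes in their comparisons with BALB/c females, among them Ly6a, Apobec3, Hspa1b and Fcer2a, with 2 in opposite directions. Independent lists would share 2.31 and 2.91, and the simulations gave 0.1 on average. Simulations without any effect leave no true differences to call, and independent lists assume separate libraries. Neither therefore measures how much of an overlap comes from the shared libraries. The 3 shared libraries could not be divided between the comparisons, so part of either overlap can come from them. The 43 genes were 17 without BWF1 male 3, 18 after thinning to equal depth and 7 with library size only.

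**Figure D4:**
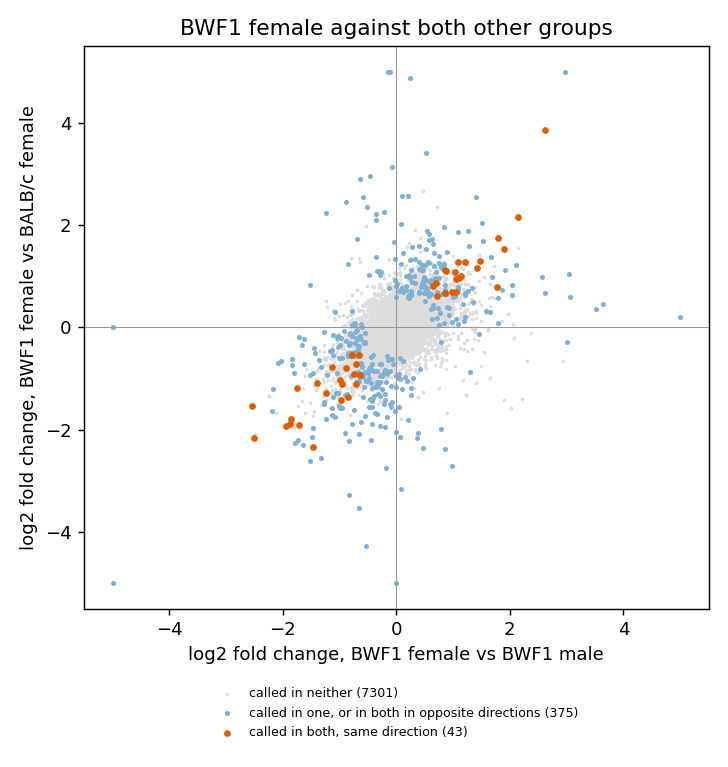
Log2 fold change of each tested gene in BWF1 females against BWF1 males (horizontal) and against BALB/c females (vertical), with the 43 genes called in the same direction in both, 375 called in one or in opposite directions and 7301 in neither marked by colour. Values beyond 5 are drawn at 5, which applies to 8 genes, and the 43 shared genes divide into 21 higher and 22 lower in BWF1 females.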

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

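The test in this part was chosen after the result was seen. Alignments not assigned to a counted gene were not unique, overlapped no counted feature or were ambiguous, and the comparisons do not use them. In both BWF1 groups they stood out from the BALB/c libraries. They made up 98.5% ± 0.168 (SD, n = 3; 98.4% to 98.7%) of all alignments in BWF1 females and 98.2% ± 0.323 (98.0% to 98.6%) in BWF1 males, against 97.4% ± 0.369 (97.2% to 97.9%) in BALB/c females. The share overlapping no counted feature was 38.2% ± 1.18, 40.7% ± 1.73 and 40.0% ± 2.34 in the same order. The share that was not unique was 60.3% ± 1.32, 57.5% ± 1.77 and 57.4% ± 2.12. For the share assigned to genes, an exact two-sided permutation test gave p = 0.1 for each BWF1 group against BALB/c females, the smallest p that 3 against 3 allows, and p = 0.3 between the BWF1 groups. With groups of 3, single libraries were not tested for standing apart from their group.

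Beside this, 1 gene, Lars2, held most of the counts within genes in 8 of the 9 libraries. A candidate explanation is ribosomal RNA reads placed on Lars2. In a comparison with the annotated transcripts, the Lars2 transcripts had 0 matches of at least 50 bases to annotated ribosomal RNA, but the annotation holds no 28S entry. They shared 72 bases at 98.6% identity with Gm15564, another gene. The annotation therefore cannot decide the origin of these reads, and the design gives no biological explanation that was tested. Lars2 itself was not called between BWF1 females and males (edgeR adjusted p = 0.725).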

How the results depend on the processing

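Removal of Lars2, Ccnb1ip1 and Ccdc107, thinning to equal depth, and ORIG libraries only were added after the data were seen. Of 230 values for named genes, RLE factors changed the call of 0, no count filter added 8, and the stricter filter ended 1. Calls ended for 68 with DESeq2, 66 with library size only, 100 in the test against a fold of 1.5 and 35 with the file-name tag. Between BWF1 females and males, 246 genes were called by limma-voom, 172 with RLE, 174 with upper-quartile factors and 186 with the tag, all within 1.5 times of 169. The count was 108 with DESeq2, which gave an adjusted p to 3412 genes only, and 98 with only the 2 groups compared and 99 with RL libraries only, both fits on fewer libraries. It was 304 with no count filter, which tests more genes, and 24 against a fold of 1.5, which asks for a larger change. It was 60 after thinning, which removes counts, and 59 with library size only. For BWF1 against BALB/c females it was 152 with DESeq2, 130 with library size only, 68 against a fold of 1.5, 160 with the tag and 154 after thinning. For BWF1 males against BALB/c females it was 176 with DESeq2, 650 with limma-voom, 510 with no count filter, 76 against a fold of 1.5, 153 with the tag, 435 without Lars2, Ccnb1ip1 and Ccdc107, and 143 after thinning. The 43 shared genes became 7 with library size only, 73 with no count filter, 3 against a fold of 1.5 and 18 after thinning. For limma-voom, DESeq2 in the comparisons with BALB/c females, the tag and the removal of Lars2, the cause was not tested. Library size only counts Lars2 in each total. The TMM factor was lowest in BWF1 male 1 (0.530), where Lars2 held 76.6% of gene counts. It was highest in BALB/c female 2 (1.40), where Lars2 held 42.3%. Scaling by library size only thus carries differences in the Lars2 share into all other genes. How much of the change in calls this explains was not tested. Leaving out each library gave 58 to 198, 184 to 370 and 119 to 393 genes in the 3 comparisons and 17 to 52 shared genes. Of the named genes called, 33 of 61, 20 of 71 and 23 of 66 lost their call without at least 1 single library. Of the list tests, 41 of 84 passed with the preset correlation and 0 with an estimated correlation, where 20 had an unadjusted p under 0.05. With a replicate block, 118, 255 and 240 genes, 35 shared genes and 42 list tests were called. Profiles with the same replicate number correlated at −0.0912 to 0.0589, with 0 of 9 pairs over 0.1. That gives no sign of pairing by number, but counting error at this depth lowers such correlations, so pairing is not excluded.

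Directions reversed in 7 values, none of them called in either fit, and the cause was not tested. For Tlr7 between BWF1 and BALB/c females, −0.19 became 0.19 with the tag, 0.0407 with ORIG libraries only, and ran from −0.38 to 0.0295 without single libraries (0.0295 without BWF1 female 1, 0.0219 without BALB/c female 3). Adgre1 between BWF1 females and males, at −0.13, ran from −0.29 to 0.26, the latter without BWF1 male 3. Cd163 between BWF1 and BALB/c females became −0.11 with ORIG libraries only, where 1 BWF1 female library is assumed to vary like the other groups, and Gm26992 became −0.0727 with library size only. Depth limits the fold changes that can be called: at a fold change of 2 the self-test recovered 44.5%, 47.8% and 56.1% of changed genes in the 3 comparisons.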

Other observations

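All tests in this part were chosen after the results were seen, except the counts of other splits. The families below were picked after the calls were seen, and the rule for reading their tests was tightened after a first run. Each was tested with camera, adjusted over 15 family tests, of which 7 pass with the preset correlation and 0 with an estimated correlation, where 2 have an unadjusted p under 0.05. Splicing factors were higher in BWF1 females than in BWF1 males: 10 of 107 rose, among them Srsf5, Luc7l3, Pnn and Hnrnph1 (camera adjusted p = 3.36e-05; median log2 fold change 0.21, and 0.39 with library size only; adjusted p = 0.294 with an estimated correlation). Ribosomal protein genes were lower, with 10 of 80 called, such as Rps26 and Rps29 (adjusted p = 5.39e-11; median −0.35, and −0.14 with library size only; adjusted p = 0.414 with an estimated correlation). Oxidative phosphorylation genes (adjusted p = 0.23; median −0.07) and proteasome genes (adjusted p = 0.755; median −0.05) did not pass in this comparison. Both medians turned positive with library size only (0.13 and 0.12), a scaling that moved the median of all genes by 0.16, so the turn follows from the scaling. Splicing factors were higher in BWF1 females than in BALB/c females too, with 13 of 107 called higher and Rbm3 lower (adjusted p = 0.000272; adjusted p = 0.294 with an estimated correlation). Their median of 0.18 became −0.11 with library size only, which moved the median of all genes by −0.29, so they stayed above it.

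Chaperones of the endoplasmic reticulum, which fold secreted and membrane proteins, were higher in BWF1 males than in BALB/c females, where plasma cell markers were higher too: 7 of 18 rose, among them Hsp90b1, Pdia4, Hyou1 and Calr (camera adjusted p = 7.32e-09; median 0.63, and 0.07 with library size only; adjusted p = 0.327 with an estimated correlation). Calr lost its call without BALB/c female 2 (edgeR adjusted p = 0.09), and Calr and Pdia4 with library size only. In BWF1 females against BALB/c females, 5 of 18 rose (adjusted p = 5.53e-05; median 0.40, and 0.11 with library size only; adjusted p = 0.414 with an estimated correlation). Ribosomal protein genes had a median of 0.37 in BWF1 males against BALB/c females, with 12 of 80 higher (adjusted p = 1.73e-11; adjusted p = 0.414 with an estimated correlation), and −0.16 with library size only, a scaling that moved the median of all genes in this comparison by −0.44. Oxidative phosphorylation genes passed in this comparison (adjusted p = 0.00514; adjusted p = 0.433 with an estimated correlation), with a median of 0.18 that became −0.31 with library size only. Both families stayed above the median gene under that scaling. Whether the families move as sets stays open, since 0 of the 15 tests pass with an estimated correlation.

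Gm26992 (ENSMUSG00000098078, chromosome X, 103422010 to 103481705) overlaps Xist (103460366 to 103483254) on the opposite strand. It had at least 3 counts in 6 of 6 female libraries and 0 over the male ones, at least 64.5-fold higher in BWF1 females than in BWF1 males (15.2-fold without BWF1 male 3, the deepest library). This is consistent with Xist reads counted on an overlapping gene, since female cells transcribe Xist from the inactive X chromosome and the counting may not have used the strand. Counts on Ccnb1ip1, at 6610 ± 2014 CPM in BWF1 females, 7436 ± 3164 in BWF1 males and 5092 ± 1831 in BALB/c females, and on Ccdc107, at 3893 ± 554, 4317 ± 873 and 4252 ± 1102 CPM, stand on genes that overlap the RNA genes Rpph1 and Rmrp.

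The immediate early and heat shock list was lower in both BWF1 groups than in BALB/c females. The tables argue against the file-name tag as the cause: within BWF1 the RL libraries exceeded the ORIG libraries by 0.0121 in mean log2 CPM over the list (SD over the 6 BWF1 libraries 0.230), while BWF1 lay at −0.82 from BALB/c. After thinning to equal depth, the median of BWF1 against BALB/c females was −0.83. Thinning keeps each gene's expected share of its library, so it cannot exclude a bias that goes with depth. A difference in handling or collection day between the strains may also lie behind the lower list. By the mean over the list, 6 of 6 BWF1 libraries lay below the lowest BALB/c library, which strain and handling would both give. The labels give no days, so the 2 cannot be told apart, and a difference between the strains remains untested.

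T cell and natural killer cell markers were lower in BWF1 females than in BWF1 males. Against BALB/c females, the T cell list was lower in BWF1 females by camera with the preset correlation, and the natural killer list did not pass. By that test both lists were higher in BWF1 males than in BALB/c females. After thinning, the median was −0.80 for the T cell list and −2.16 for the natural killer list. These medians cover only members among the 5037 genes that passed the count filter after thinning, against 7719 before. They may therefore rest on fewer members than the medians without thinning. Thinning also keeps each gene's expected share of its library, so neither median can exclude a bias that goes with depth. Dilution of all lymphocytes by other cells would lower B and T cell markers alike. Yet the T cell score minus the B cell score was lower by 0.82 in BWF1 females than in BWF1 males (highest female −2.73, lowest male −2.16). BALB/c females 1 to 3 stood at −2.67, −3.01 and −2.67, so on this score the males stood apart from both female groups. Without BWF1 male 1, the library with the highest erythroid markers among males, the medians were −0.88 and −1.44, so that library alone does not produce the pattern. A difference in cell composition between the sexes, in the cells passing the sort that the sample labels name, or in expression within cells stays open and was not tested.

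For each comparison, the 6 libraries were also divided into 3 and 3 in all 10 ways, with the third group kept. In each comparison 1 of the 10 splits, the real one, gave as many genes. The real split gave 169 genes for BWF1 females against males, where the highest other split gave 5, 295 for BWF1 against BALB/c females, where the highest other gave 0, and 272 for BWF1 males against BALB/c females, where the highest other gave 1. With 10 splits, no share under 0.05 can be reached.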
